A study of Arabidopsis thaliana with 236 samples.

How the data were processed

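RNA from sorted Arabidopsis Col-0 root cells was measured on 236 custom NimbleGen expression arrays designed on the TAIR10 genome release. Per the labels' protocols, plants grew for 9 days in 16 h light and 8 h dark on 0.1 mM KNO3, were moved or inoculated at dawn, and whole roots were turned into protoplasts and sorted by fluorescence for cortex or pericycle cells. The series record names pericycle and cortical cells in one sentence and epidermal and cortical cells in another, and its hours include 7 h but neither 8 nor 36 h; the sample titles were used for both. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, amplified with a NuGEN Ovation Pico WTA kit and labelled with Cy3. The labels give an age of 12 days beside 9 days of growth, and they do not name the marker lines, the slides or the batches.

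The values are deposited as log2 intensities made by RMA, per the submitters' processing notes; the RMA software and its version are not given in the sources used here. The deposited table has 31524 rows without missing values, from 3.69 to 15.53, and array medians from 8.44 to 9.23. The arrays were chosen after the authors' quality control, per the submitters' processing notes. Nothing was taken from raw scans, so background and probe quality were not examined.

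Rows of the same locus were averaged (3675 of 27143 loci had several), no other scaling was applied, and no gene was left out. Symbols came from the RefSeq annotation of TAIR10.1, which holds 26555 of the loci and gives a symbol for 10363, and other loci are printed by identifier. Cell type, treatment, hour and replicate number came from the sample titles. Within-group pairs correlating above 0.995 were averaged and counted as 1 array, which applied to 1 pair and left 235 arrays. Replicate numbers were checked for pairing between treatments: the residual correlations of arrays with the same number were 0.0049, 0.00081 and 0.0032 in cortex and 0.020, 0.0024 and 0.044 in pericycle. Different numbers gave -0.0012, -0.0019 and -0.00090 in cortex and 0.013, -0.032 and -0.015 in pericycle. These means are small and arrays were not paired. In pericycle, however, 28.3% of pairs within number 3 exceeded 0.1, against 10.3 and 12.7% for number 3 with 1 and 2. Some structure was thus tied to number 3 there.

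A linear model with 1 mean for each of the 80 groups of cell type, treatment and hour was fitted with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with moderated variances (prior df 3.04, residual df 155) and Benjamini-Hochberg adjustment; calls are loci with an adjusted p below 0.05. Contrasts averaged the same-hour differences over 13 hours, for pericycle against cortex over the standard hours and 0 h (14 hours), for each treatment against standard, for the difference of these responses between cell types, and for nitrogen against rhizobium. Other contrasts took the early (1 to 6 h), middle (8 to 16 h) and late (20 to 48 h) windows and, for the clock, 12 h against the mean of 24 and 48 h on standard arrays. Moderated F tests took all 13 hours at once for each treatment and for the standard course against 0 h.

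The groups, contrasts, 26 gene lists, tests, naming rule and most other settings listed below were fixed before the data were examined. The lists have 334 members: nitrate-induced, nitrogen-starvation, phosphate starvation, iron deficiency, immune response, LysM receptor, jasmonate, auxin response, cytokinin response, ethylene, abscisic acid, lateral root initiation, cell cycle, clock morning, clock evening, heat shock, touch and wounding, phenylpropanoid and flavonoid, and markers of cortex, endodermis, epidermis and root hair, green tissue, pericycle and stele, phloem, root cap and xylem. Each list was tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation. Member counts use the adjustment over all loci, and counts adjusted over the list alone are given beside them. Overlaps of calls were set against independent lists and, for correlations and covariances, against 20 simulations of unchanged groups sharing the standard arrays.

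Genes were named by a rule: for each contrast, the 10 largest log2 changes in each direction among calls whose same-hour difference had the sign of the mean at 10 or more of 13 hours (11 of 14 for cell type), for each F test the 5 smallest p not already named, and any member of a list. The text names a part of these. Numbers after ± are SE for changes and SD for array values. In treatment comparisons, rose and fell mean higher or lower than on the standard arrays of the same hour, and do not say which arrays moved.

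The fit was tested on simulated data with 200 changed genes among 27143. For the nitrogen mean response in pericycle it found 32.8, 80.6 and 97.0% of changes of 0.5, 1 and 2 log2 units with 9 false calls, and for the same response in cortex 28.4, 67.2 and 97.0% with 4. The F tests found 17.9, 53.7 and 95.5% in pericycle and 8.96, 34.3 and 86.4% in cortex. A jasmonate list shifted by 0.5 in the nitrogen mean response in pericycle passed camera (adjusted p = 3.5e-67) and none of the other lists did. The simulated genes were drawn independently, while the estimated correlation of the real jasmonate list was 0.30. The simulation therefore does not test how often camera calls an unshifted list of correlated genes.

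Results were also computed with an adjusted p below 0.01, a change of at least 1 log2 unit, each replicate number or time point left out, each cell type fitted alone, array weights, a trended robust prior, median centring, quantile normalization, loci above the 25th or 50th percentile, separate tests of the rows of a locus, a replicate block, fry, list members in 1 list only, and split standard arrays. A heat shock covariate, leaving out the 10 arrays of lowest correlation, and counting the near-identical pair as 2 arrays were chosen after the data were seen. List tests in single windows were not recomputed under these settings, apart from fry and list members in 1 list only. Label splits drew 100 regroupings for each count. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.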

Results

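Gene expression was measured in sorted root cells of Arabidopsis thaliana (accession Col-0) after a change of nitrate supply or contact with a soil bacterium. Root protoplasts were sorted by fluorescence to collect cells with a green fluorescent protein marker in the cortex, the ground tissue outside the endodermis, or in the pericycle, the layer just inside the endodermis from which lateral roots start. Seedlings had grown for 9 days on 0.1 mM KNO3. At dawn they went to fresh 0.1 mM KNO3 (standard) or to 5 mM KNO3 (nitrogen), or to fresh 0.1 mM KNO3 with a Sinorhizobium meliloti culture at an OD600 of 0.8 (rhizobium). S. meliloti is a nodule symbiont of legumes, and Arabidopsis forms no nodules with it. Cells were taken at 0 h, before the treatment, and at 1, 2, 4, 6, 8, 10, 12, 14, 16, 20, 24, 36 and 48 h, so each treatment can be set against the standard arrays of the same hour in each cell type. The hours and cell types are those of the sample titles. The series record lists 7 h and neither 8 nor 36 h, and it speaks of pericycle and cortical cells in one sentence and of epidermal and cortical cells in another, so what the pericycle arrays hold rests on the titles.

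The single-colour arrays, 110 of cortex and 126 of pericycle cells, formed 80 groups of 2 to 5 arrays. Of the cortex arrays, 3 were taken at 0 h, 37 were standard, 32 nitrogen and 38 rhizobium, and of the pericycle arrays 5 were taken at 0 h, 38 were standard, 41 nitrogen and 42 rhizobium. The deposited log2 values lay between 3.69 and 15.53, with array medians over all table rows from 8.44 to 9.23, and gave 27143 loci. Replicates 2 and 3 of the pericycle standard group at 16 h correlated at 0.999, with an SD of their difference of 0.12 log2. The next closest of the 244 pairs within groups correlated at 0.974 with an SD of 0.68, so that pair differed by far less than other replicates do and was averaged and counted as 1 array. The number of arrays limits the precision, and the labels do not say whether replicates came from separate plantings, so the p-values measure the spread between arrays, which may be partly technical.

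Heat shock genes were higher on most cortex standard arrays than on the treated cortex arrays. The mean of the 9 heat shock genes fixed beforehand, among them HSFA2, HSP101 and several small heat shock proteins, was 14.22 ± 0.78 (SD, n = 37) on the cortex standard arrays, 11.39 ± 0.91 (n = 32) on the cortex nitrogen arrays and 11.20 ± 1.08 (n = 38) on the cortex rhizobium arrays. Of the standard arrays all but 3 lay above the highest treated cortex array (13.30); these 3 were replicate 2 at 14 h (11.08), replicate 1 at 4 h (11.60) and replicate 2 at 2 h (12.83). The 3 cortex arrays at 0 h averaged 13.307 ± 1.395. Pericycle arrays averaged 11.91 ± 1.01 (standard, n = 37), 11.16 ± 1.09 (nitrogen, n = 41), 11.42 ± 0.97 (rhizobium, n = 42) and 11.14 ± 1.62 (0 h, n = 5). The third principal component of all arrays, with 4.47% of the variance, placed the cortex standard arrays at -63.1 ± 30.6 and the cortex nitrogen and rhizobium arrays at 1.9 ± 22.2 and 16.2 ± 13.8. Every comparison below that uses the cortex standard arrays carries this difference, and the comparison of nitrogen with rhizobium does not use them. A heat shock covariate nearly coincides with treatment in cortex. Counts and calls lost with it against the cortex standard arrays therefore cannot be assigned to heat shock or to treatment.

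**Figure D1:**
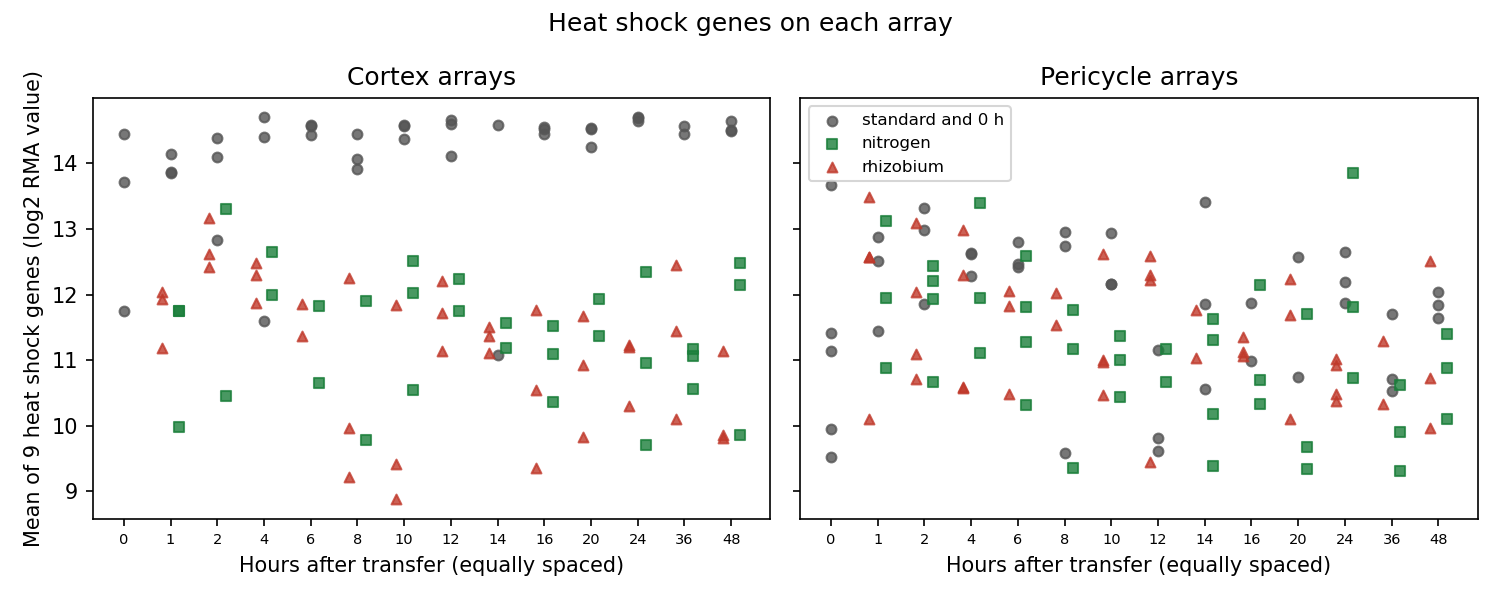
Mean log2 value of the 9 heat shock genes on each array (vertical axis) by hour after transfer (horizontal axis, hours equally spaced), with cortex arrays in the left panel and pericycle arrays in the right panel; each symbol is 1 array. Most cortex standard arrays lie near 14 (mean 14.22), above the cortex nitrogen and rhizobium arrays, except 3 of which the lowest is at 11.08, and the pericycle treatments overlap.

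Pericycle arrays carried higher levels of root hair and auxin response genes and of some pericycle and stele markers than cortex arrays, and lower levels of heat shock genes. AAP2 (AT5G09220), an amino acid permease, was higher in pericycle by log2 6.27 ± 0.36 SE (adjusted p = 6.8e-35), with means of 11.86 in pericycle and 5.59 in cortex, where its signal above background was not examined. DR4 was higher by 4.80 ± 0.28, and the pericycle and stele markers NPF7.3, which loads nitrate into the xylem, TIP2;3, an aquaporin, and PHO1, which loads phosphate into the xylem, were higher by 3.64, 2.74 and 2.54. Of the 8 pericycle and stele markers 4 were higher and 1, BOR1, was lower (-0.65). None of the 5 cortex markers passed the test, with a list median of -0.08. Of 10 endodermis markers 8 were higher in pericycle, with a median of 1.94 (adjusted p = 0.077 with an estimated correlation), led by ESB1 (4.46) and CASP1 (4.07) of the Casparian strip and MYB36 (3.40), and 7 of 9 epidermis and root hair markers were higher, with a median of 1.06, led by RHD6 (3.12) and RSL4 (2.69).

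Hormone genes also differed between the cell types. Of 19 auxin response genes 13 were higher in pericycle and none was lower, with a median of 1.097, led by GH3.2 (2.59) and IAA2 (2.197). Of 21 jasmonate genes 16 were higher and 2 lower (adjusted p = 0.068 with an estimated correlation), led by the repressor genes JAZ7 (3.71) and JAZ9 (2.81). On the arrays themselves the auxin list averaged 8.28 ± 0.27 on cortex standard, 8.81 ± 0.33 on cortex nitrogen and 8.97 ± 0.26 on cortex rhizobium arrays, against 9.27 ± 0.30 on pericycle standard arrays. All 3 root cap markers (median 1.34), 8 of 13 nitrogen-starvation genes (median 0.48, including NRT2.4 and DUR3) and 6 of 18 lateral root initiation genes (median 0.22, including LBD16 and LAX3) were higher, with adjusted p = 0.066, 0.070 and 0.068 with an estimated correlation. Lower in pericycle were all 9 heat shock genes (median -2.37), 11 of 12 green tissue genes (median -1.98, led by RBCS1B), and 6 of 11 morning clock genes (median -0.76, led by RVE7), the latter lists with adjusted p = 0.17 and 0.19 with an estimated correlation. ATHSP22.0 (-5.87 ± 0.34), EMB3111 (-4.43) and HSP23.6-MITO (-4.31) were among the 10 loci with the largest values lower in pericycle under the naming rule.

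The cell type comparison set 42 pericycle arrays against 40 cortex arrays over 0 h and the 13 standard hours. By limma's moderated test, 10630 of 27143 loci passed an adjusted p of 0.05, 5645 higher and 4985 lower in pericycle, and 3022 of them differed by at least 1 log2 unit. By camera over the 26 lists, the auxin (adjusted p = 1.2e-07), heat shock (1.4e-11), root hair (8.8e-06) and pericycle and stele lists (0.0023) held with an estimated correlation. The other calls, for endodermis, jasmonate, lateral root initiation, green tissue, morning clock, nitrogen-starvation and root cap, did not hold. With p adjusted over the list alone, 14 auxin genes, 17 jasmonate genes, 8 endodermis markers, 7 root hair markers, 4 pericycle and stele markers (1 lower), 6 lateral root genes, 8 nitrogen-starvation genes and 3 root cap markers were higher, and 9 heat shock, 11 green tissue and 6 morning clock genes were lower. Without replicate 1 the count was 5892 and BOR1 (-0.49) no longer passed, and with the heat shock mean of each array as a covariate the morning clock list turned to 0.05 and the nitrogen-starvation call ended (0.21).

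Nitrate-induced genes were higher on nitrogen than on standard cortex arrays. Of 32 such genes 19 rose and 3 fell, with a median of 0.39 (adjusted p = 0.093 with an estimated correlation), led by the transcription regulator genes LBD39 (2.85 ± 0.20, adjusted p = 2.8e-26) and BT2 (2.27 ± 0.24, adjusted p = 7.7e-15). The reductase gene RFNR2 (1.28) and the transporter genes NRT2.1 (1.21) and CLCA (1.12) rose too, while NRT3.1, which encodes a partner of nitrate transporters, fell by 1.30. HB1 (AT2G16060), which encodes a haemoglobin, was higher by 2.92 ± 0.35, with means of 12.98 on nitrogen and 10.06 on standard arrays. The largest rise was at AT1G68238 (4.51 ± 0.38). The auxin genes GH3.3 (2.37), GH3.2 (2.37) and IAA2 (1.77) were among 6 of 19 auxin response genes that rose (list median 0.27), and 4 of 5 cortex markers rose (median 1.12), including NPF6.4 (1.29), with adjusted p = 0.14 and 0.17 with an estimated correlation. Markers of other cells were higher too: the pericycle and stele marker mean was 7.17 on standard, 7.73 on nitrogen and 7.69 on rhizobium cortex arrays, and the root cap mean 6.12, 6.91 and 6.55. In the mean nitrogen response 4 of 8 pericycle and stele markers rose and 1 fell (median 0.44, camera adjusted p = 0.13), and 2 of 3 root cap markers rose (median 0.80, camera 0.15). Over 1 to 6 h the pericycle and stele list passed (median 0.65, camera 0.0090, adjusted p = 0.049 with an estimated correlation). The auxin rise is not separated from a change in the cells collected.

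Other groups were lower on nitrogen than on standard cortex arrays. All 9 heat shock genes fell (median -2.70, HSFA2 by -4.50 ± 0.34), and the loci with the largest falls included AT5G53680 (-6.63 ± 0.38), ATHSP22.0 (-5.91), BGLU27 (-5.33) and HSP70T-2 (-4.73). On cortex standard arrays 7 of the 9 had means between 14.54 (HSP17.6A) and 14.96 (HSP101), near the highest value of all arrays (15.53), so their differences are lower limits if the signal saturates there. Of 11 morning clock genes 8 fell (median -1.05, LNK2 by -1.70), and of 22 immune response genes 12 fell and 1 rose (median -0.44), with CYP81F2 at -2.36, the oxidase gene RBOHD at -1.04 and NHL10 at 1.57. These lists had adjusted p = 0.12 (morning clock) and 0.093 (immune) with an estimated correlation. The 21 jasmonate genes went both ways, 5 higher and 11 lower (camera adjusted p = 0.16).

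The cortex nitrogen response, averaged over 13 hours, passed the limma test at 9687 loci, 5680 higher and 4007 lower, of which 2551 changed by at least 1 log2 unit. By camera the heat shock list held with an estimated correlation (adjusted p = 0.0020), while the nitrate-induced (camera 6.7e-06), immune response (4.3e-05), morning clock, auxin and cortex marker calls did not. In single windows more lists held, but no window list call was recomputed with replicates or hours left out or with other scalings. Over 1 to 6 h the added lists were auxin (4 of 19 higher, median 0.56, adjusted p = 0.041 with an estimated correlation) and pericycle and stele markers (1 of 8 higher, median 0.65, 0.049). Over 20 to 48 h they were the nitrate-induced (16 higher and 2 lower, median 0.62, 0.027), nitrogen-starvation (5 of 13 lower, median -0.63, 0.019), immune (7 lower, 0.019) and cortex marker genes (3 higher, 0.028). In counts adjusted over the list alone, 21 nitrate-induced genes rose and 3 fell, 6 auxin genes and 4 cortex markers rose, and 9 heat shock, 8 morning clock and 13 immune genes fell, with 1 immune gene higher. Higher calls made up 58.6% as deposited and 68.9% after centring each array on its median. With the heat shock covariate the count was 5074 and without replicate 2 it was 6411, with LNK2 (-1.14) and NRT3.1 (-1.16) no longer past the threshold, and the auxin and cortex marker calls ended in a fit of cortex arrays alone. The morning clock call ended with the covariate (-0.32) and the cortex marker call without replicate 1 (0.95).

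On pericycle nitrogen arrays nitrate-induced genes were higher, and genes of nitrogen starvation and jasmonate lower, than on standard arrays. Of 32 nitrate-induced genes 19 rose and 1, NRT3.1 (-1.70), fell, with a median of 0.33. Among them were AT3G25790 (3.12 ± 0.37, 12.04 against 8.92 on standard arrays), the transcription factor genes HRS1 (1.85), LBD39 (1.39) and TGA1 (1.14), and G6PD3 (1.34). HB1 was higher than on standard arrays by 2.85 ± 0.32 and GSTF14, a glutathione transferase gene, by 2.95 ± 0.41, and the largest difference was at AT5G62720 (3.90 ± 0.28). For HB1 the standard arrays were the ones with lower values at late hours. Of 13 nitrogen-starvation genes 8 fell (median -0.50): the urea transporter gene DUR3 by -2.98 ± 0.37, the glutamine synthetase gene GLN1;4 by -2.07 ± 0.14, GDH3 by -1.40, the nitrate transporter gene NRT2.4 by -1.36 and the ammonium transporter gene AMT1;1 by -0.82.

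Jasmonate genes fell broadly in nitrogen-treated pericycle, 18 of 21 with none higher and a median of -0.68, including JAZ7 (-2.40 ± 0.38), JAZ9 (-1.93) and the biosynthesis genes AOC1 (-1.19) and LOX3 (-1.06). Of 12 abscisic acid genes 6 fell (median -0.45), including HAI1 (-1.05), and 5 of 9 root hair markers rose (median 0.58), led by PRP3 (1.48), with adjusted p = 0.079 and 0.25 with an estimated correlation. Since root hair genes mark another cell type, that rise is not separated from a change in the cells collected. Of 9 heat shock genes 3 were lower, with a median of -0.67 (adjusted p = 0.28 with an estimated correlation). The largest falls included AT3G59580 (-5.13 ± 0.35), listed in the reference as NIN-like protein 9, AT5G56840 (-3.93), AAP2 (-3.31 ± 0.37), the glutamate receptor-like gene GLR3.4 (-3.10), LBO1 (-2.88) and the homeobox gene HB53 (-2.87).

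The pericycle nitrogen response set 41 nitrogen against 37 standard arrays, and 5327 loci passed the limma test, 2313 higher and 3014 lower, 1043 of them by at least 1 log2 unit. The nitrate-induced (camera adjusted p = 2.7e-14), nitrogen-starvation (1.1e-07) and jasmonate (2.3e-17) lists held with an estimated correlation. The abscisic acid (camera 2.6e-04), root hair and heat shock calls did not. By p-values adjusted over the list alone, 19 nitrate-induced genes rose and 2 fell, 5 root hair markers rose, and 8 nitrogen-starvation, 18 jasmonate, 6 abscisic acid and 7 heat shock genes fell. Higher calls were 43.4% as deposited and 55.1% after centring. Without replicate 1 the count was 1759, without replicate 2 NRT2.4 (-0.55) no longer passed, and without replicate 3 the root hair call ended (0.39).

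**Figure D2:**
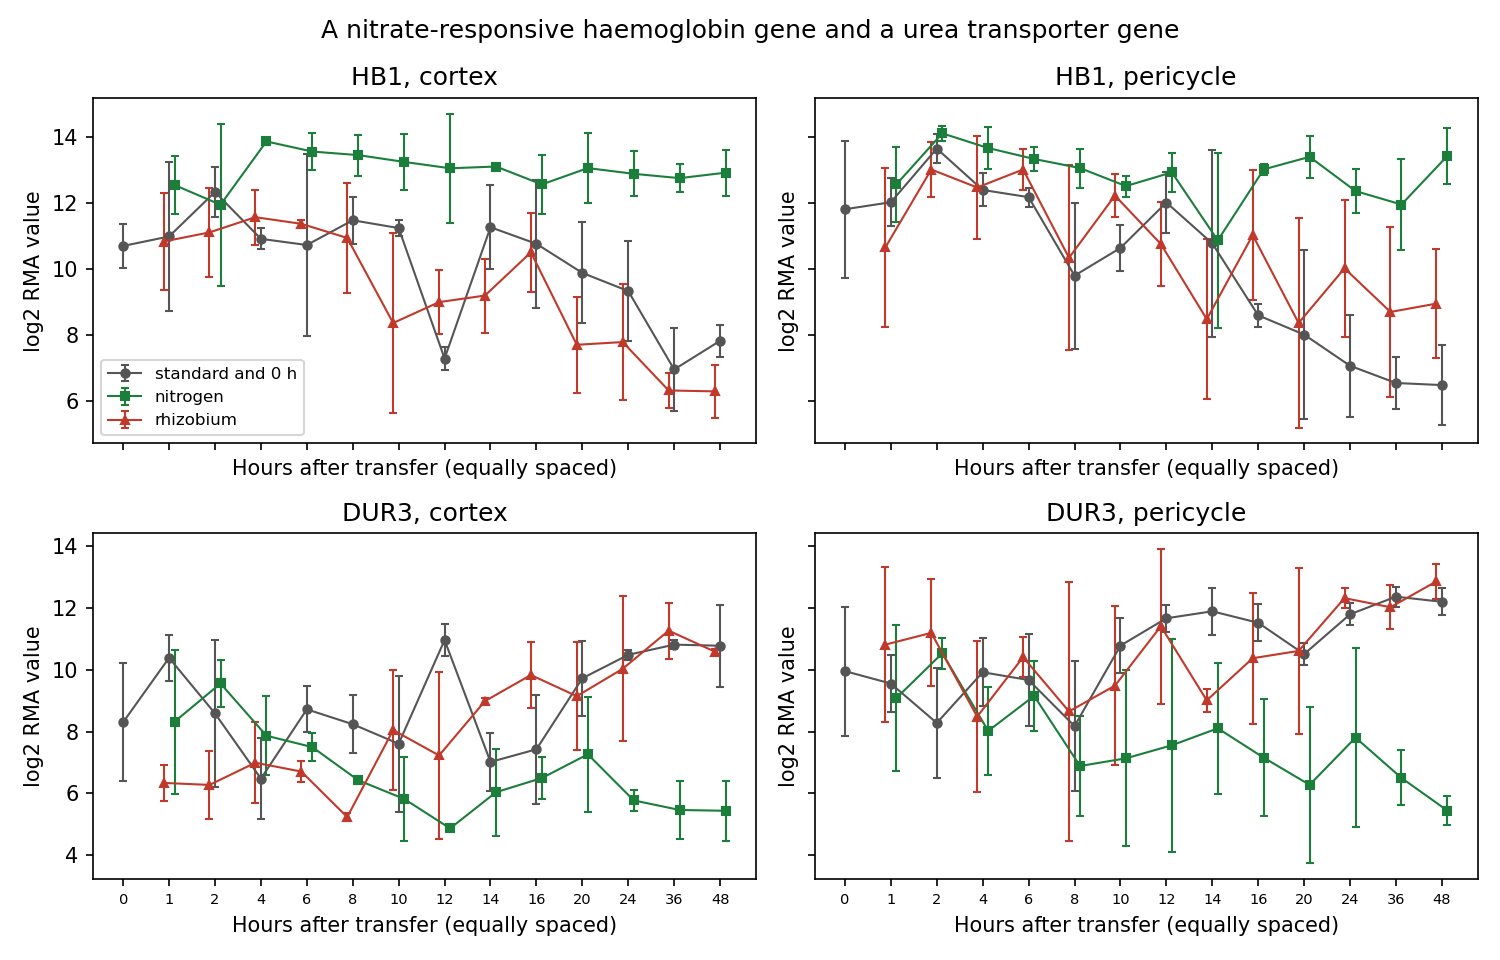
Mean log2 value ± SD (vertical axis) of HB1 (upper panels) and DUR3 (lower panels) by hour (horizontal axis, hours equally spaced) in cortex (left) and pericycle (right), for 2 to 5 arrays a point. HB1 stayed high on nitrogen arrays while it was lower at late hours on standard arrays, 6.47 ± 1.203 against 13.41 ± 0.85 in pericycle at 48 h, and DUR3 at 48 h was 12.21 ± 0.43 on standard and 5.45 ± 0.48 on nitrogen arrays.

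The nitrogen response was present in each part of the time course in both cell types. In cortex 1246 loci were higher and 1014 lower over 1 to 6 h, 2342 and 2168 over 8 to 16 h, and 1805 and 2176 over 20 to 48 h. In pericycle the counts were 840 and 955, 634 and 1058, and 763 and 1587. The balance of higher and lower calls depends on the scaling of the arrays. After centring on array medians the share of higher calls over 1 to 6 h in pericycle went from 46.8% to 73.7%, and that over 8 to 16 h in cortex from 51.9% to 66.6%. Jasmonate genes in pericycle passed in 13 of 21 members over 8 to 16 h (median -0.74) and 17 over 20 to 48 h (median -1.05), and no list call for them was made over 1 to 6 h. Abscisic acid genes in pericycle fell in 8 of 12 over 20 to 48 h (median -1.11, adjusted p = 0.0027 with an estimated correlation). A moderated F test over the 13 hours found 4506 loci changed at any time in cortex and 2832 in pericycle. Apart from the loci picked for the largest mean changes, the 5 of smallest p included AT1G67540 and the auxin gene IAA2 (2.94 at 10 h) in cortex, and GLN1;4 (-5.04 at 48 h) and AIB (-4.48 at 36 h) in pericycle. In a fit of each cell type alone the any-time counts became 8643 in cortex and 863 in pericycle. Without replicate 3 the early pericycle count was 70, and without replicate 2 the early cortex count was 443.

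**Figure D3:**
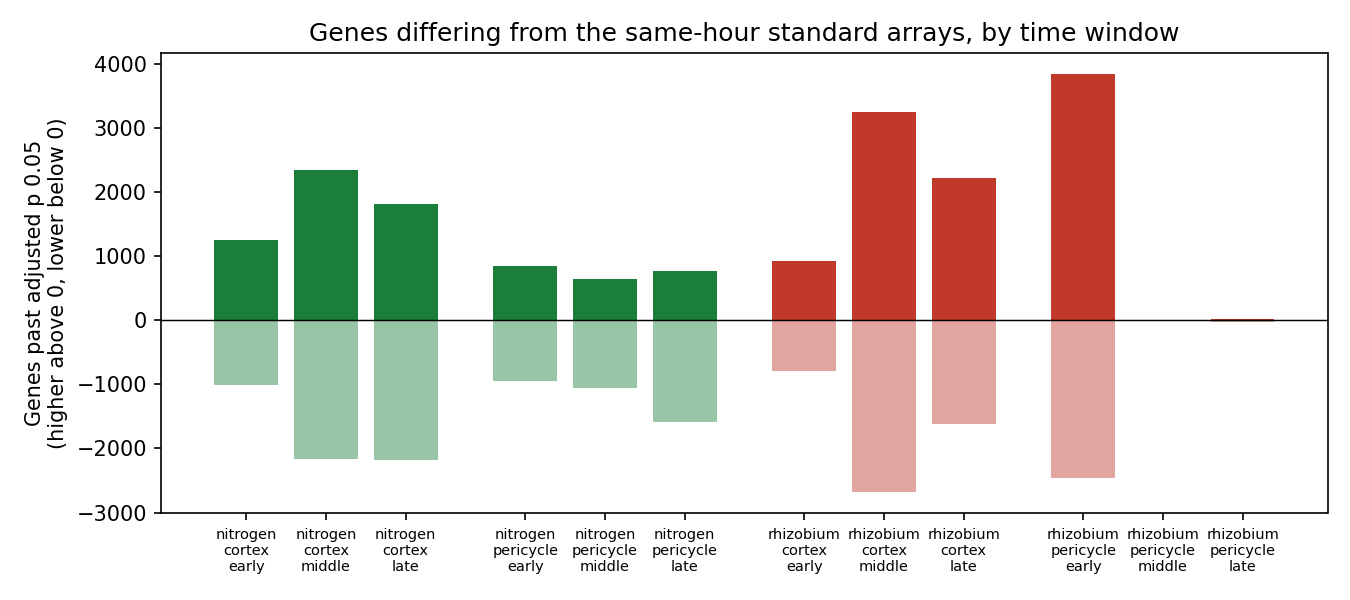
Number of loci past an adjusted p of 0.05 (vertical axis; higher above 0 and lower below 0) in each treatment, cell type and time window (horizontal axis; early 1 to 6 h, middle 8 to 16 h, late 20 to 48 h), against the standard arrays of the same hours. Rhizobium calls in pericycle lie in the early window, with 3838 higher and 2454 lower, against 25 in the middle and 47 in the late window.

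The nitrogen response differed between the cell types in members of the jasmonate, auxin, immune and heat shock lists, by a test of the difference of the responses, but every list call in it was lost (adjusted p = 0.061 with an estimated correlation for auxin and for heat shock, 0.30 for immune, 0.35 for jasmonate). JAZ7 rose by 1.94 in cortex and fell by 2.403 in pericycle, a difference of -4.35 ± 0.55 (adjusted p = 9.6e-11), and 8 of 21 jasmonate genes had a lower response in pericycle and 1, LOX2, a higher one. IAA2 (-1.93), GH3.3 (-2.23) and 3 more of 19 auxin genes had a lower response in pericycle. CYP71A12 (2.81) and CYP81F2 (2.31) were among 6 immune response genes with a higher response in pericycle. All 9 heat shock genes differed, with a median of 2.09, and the largest differences included ATHSP22.0 (5.98 ± 0.51) and BGLU27 (5.20). The difference passed at 6175 loci, 2705 higher and 3470 lower. Adjusted over the list alone, 5 auxin and 8 jasmonate genes were lower, 8 immune and 9 heat shock genes higher. Both values of each difference use the standard arrays whose heat shock means differ between cell types, and without replicate 1 the count was 3421. LOX2 no longer passed without replicate 1 (1.05) or 3 (0.85) or the 4 h (0.77), 6 h (0.71) or 8 h (0.74) arrays, nor CYP71A12 without replicate 3 (1.97).

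Cortex rhizobium arrays had lower levels of heat shock genes than cortex standard arrays, and members of the auxin, jasmonate, green tissue and morning clock lists differed, whose calls were lost at adjusted p = 0.057, 0.41, 0.39 and 0.14 with an estimated correlation. Of 19 auxin response genes 9 rose and 1 fell, with a median of 0.36; the rises included IAA5 (3.29 ± 0.43), GH3.2 (2.77 ± 0.24) and IAA2 (1.94 ± 0.10). As with nitrogen, this rise is not separated from a change in the cells collected. The pericycle and stele marker mean (7.69 against 7.17) and the root cap mean (6.55 against 6.12) were higher on rhizobium than on standard arrays too. Neither list passed camera (0.22 and 0.46). Of 21 jasmonate genes 8 rose and 1 fell (median 0.15), including JAZ7 (3.54 ± 0.38), JAZ9 (2.51) and AOC1 (1.53). CLE1 (AT1G73165), a signalling peptide gene, rose by 3.96 ± 0.42, LEA7, a late embryogenesis abundant protein gene, by 3.75 ± 0.33, and the largest rise was at AT4G15990 (4.56 ± 0.61). NIA1, a nitrate reductase gene, fell by 0.44, and the nitrate-induced list as a whole went both ways with 7 higher and 9 lower (camera adjusted p = 0.75).

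All 9 heat shock genes were lower on rhizobium than on standard cortex arrays (median -3.21, HSP17.6II by -4.15), and ATHSP22.0 (-6.35 ± 0.35) and HSP23.6-MITO (-4.87) had some of the largest falls of all loci. Of 12 green tissue genes 9 fell (median -1.54), including the Rubisco small subunit genes RBCS1B (-2.35) and RBCS2B (-2.14). On single arrays the green tissue mean spread widely, at 9.38 ± 1.98 on cortex standard and 7.93 ± 1.15 on cortex rhizobium arrays. Of 11 morning clock genes 8 fell (median -1.28, PRR7 by -1.83), and of 22 immune genes 9 fell and 3 rose (median -0.30, adjusted p = 0.39 with an estimated correlation), with CYP81F2 at -2.06 and NHL10 at 2.505.

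The cortex rhizobium response passed at 10264 loci, 5913 higher and 4351 lower, 2730 of them by at least 1 log2 unit, over 38 rhizobium and 37 standard arrays. The heat shock list held with an estimated correlation (adjusted p = 5.4e-04). The auxin (camera 0.0016), morning clock, green tissue, immune and jasmonate calls did not, but over 1 to 6 h alone the auxin list held (6 of 19 higher, median 0.15, camera 0.0011, adjusted p = 0.032 with an estimated correlation). With p adjusted over the list alone, 10 auxin genes rose and 2 fell, 8 jasmonate genes rose and 1 fell, 9 green tissue, 9 heat shock and 8 morning clock genes fell, and 11 immune genes fell and 3 rose. By window 919 loci were higher and 798 lower over 1 to 6 h, 3252 and 2683 over 8 to 16 h, and 2215 and 1627 over 20 to 48 h. Centring took the early share of higher calls from 53.5% to 45.2%. By the F test 3654 loci changed at any time, with the smallest p, apart from the loci picked for the largest mean changes, at HSP70T-2 (-6.18 at 48 h). With the heat shock covariate the mean response count was 5405 and the any-time count 763, and without replicate 2 the former was 6788. The morning clock (-0.48) and green tissue (-0.70) calls ended with the covariate.

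Members of the root hair, phenylpropanoid and cell cycle lists differed between pericycle rhizobium and standard arrays, and the list calls were all lost at adjusted p = 0.55 with an estimated correlation. Of 9 root hair markers 6 rose (median 0.72), led by COBL9 (1.24 ± 0.32, adjusted p = 0.0026), and 5 of 14 phenylpropanoid and flavonoid genes rose (median 0.41), led by TT7 (1.60 ± 0.43) and 4CL3 (1.09). Root hair genes mark another cell type, and their rise is not separated from a change in the cells collected. The endodermis mean was 9.52 ± 1.71 on rhizobium and 9.10 ± 1.35 on standard arrays and the green tissue mean 8.12 ± 1.18 and 7.46 ± 1.01, though neither list passed camera (0.79 and 0.070). The cell cycle genes MCM4 (-1.44 ± 0.30), MCM5 (-0.94) and MCM7 (-0.75), subunits of the replicative helicase, fell, with no other of 25 members past the test (median -0.33). Of 22 immune genes 6 rose, among them PR1 (0.71). Of 8 LysM receptor genes, a family that includes receptors for chitin and Nod factors, 3 rose: LYK2 (0.88), LYK4 (0.86) and LYK5 (0.70). Neither list passed camera (adjusted p = 0.086 and 0.27). The largest rises were at AT5G57625 (2.23 ± 0.40) and GEA6 (2.04), and the largest falls included AT2G43530 (-2.65 ± 0.54), scpl16 (-2.003) and FRS10 (-1.74).

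The pericycle rhizobium response passed at 5936 loci, 3536 higher and 2400 lower, of which 659 changed by at least 1 log2 unit, over 42 rhizobium and 37 standard arrays. Every list call was lost with an estimated correlation, at adjusted p = 0.55 with an estimated correlation for root hair, phenylpropanoid, cell cycle and heat shock (2 of 9 lower, median -0.43). In counts adjusted over the list alone, 7 root hair, 5 phenylpropanoid, 6 immune and 3 LysM receptor genes rose, and 2 cell cycle and 2 heat shock genes fell. The share of higher calls was 59.6% as deposited and 81.5% after centring on array medians, which moved the median change of all loci by 0.12 (from 0.03 to 0.15). Over 1 to 6 h 3838 loci were higher and 2454 lower, against 8 and 17 over 8 to 16 h and 23 and 24 over 20 to 48 h, with 2646 and 3697 loci under an unadjusted p of 0.05 in the later windows. Centring took the share of higher calls from 61.0% to 82.2% over 1 to 6 h, from 32.0% to 70.4% over 8 to 16 h (19 higher and 8 lower), and left no call over 20 to 48 h. The any-time F test found 4035 loci, with the smallest p, apart from the loci picked for the largest mean changes, at ADL6, and 817 in a fit of pericycle arrays alone. Without replicate 3 the mean response count was 1200, the early count 534 and the any-time count 193, and the calls of TT7 (0.99), 4CL3 (1.06), PR1 (0.50), LYK4 (0.66), LYK5 (0.47), MCM5 (-0.85) and scpl16 (-1.54) ended. That of MCM7 (adjusted p = 0.046) ended without replicate 1, 2, 3 or 4 (-0.71 to -0.78), without single hours (-0.55 without 12 h) and under centring or quantile normalization (-0.63 and -0.75), and that of 4CL3 without 6 h (0.76). Without the 2 h arrays the mean response count was 3943. The cell cycle call ended without replicate 3 (-0.07) or 12 h (-0.22), the phenylpropanoid call without replicate 4 (0.36) or 6 h (0.34), and the heat shock call without replicate 3 (-0.32) or 4 (-0.40), 6 h (-0.31), 14 h (-0.46) or 24 h (-0.35).

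The rhizobium response differed between the cell types at 9060 loci by the test of the difference, 4419 higher and 4641 lower in pericycle, a balance that turned with scaling (48.8% higher as deposited, 56.3% after centring). No list call held, with adjusted p = 0.065 with an estimated correlation for heat shock, 0.14 for auxin, 0.39 for immune and between 0.45 and 0.50 for green tissue, phenylpropanoid and jasmonate. JAZ7 (-4.62 ± 0.54) and IAA5 (-4.23 ± 0.61) had lower responses in pericycle, as did SWEET17 (-4.21), a sugar transporter gene, with 10 of 21 jasmonate genes lower and 1 higher and 9 of 19 auxin genes lower and 3 higher. RBCS1B (3.73) was among 10 of 12 green tissue genes with a higher response in pericycle, PAL1 (1.395) among 8 of 14 phenylpropanoid genes, and CYP81F2 (2.68) among 11 of 22 immune genes. All 9 heat shock genes differed (median 2.56). Adjusted over the list alone the counts were 10 green tissue, 8 phenylpropanoid, 12 immune and 9 heat shock genes higher, and 10 jasmonate and 9 auxin genes lower. The cortex standard arrays with their high heat shock mean enter every difference, and without replicate 3 the count was 4745, while the jasmonate call ended without replicate 1 (-0.23).

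**Figure D4:**
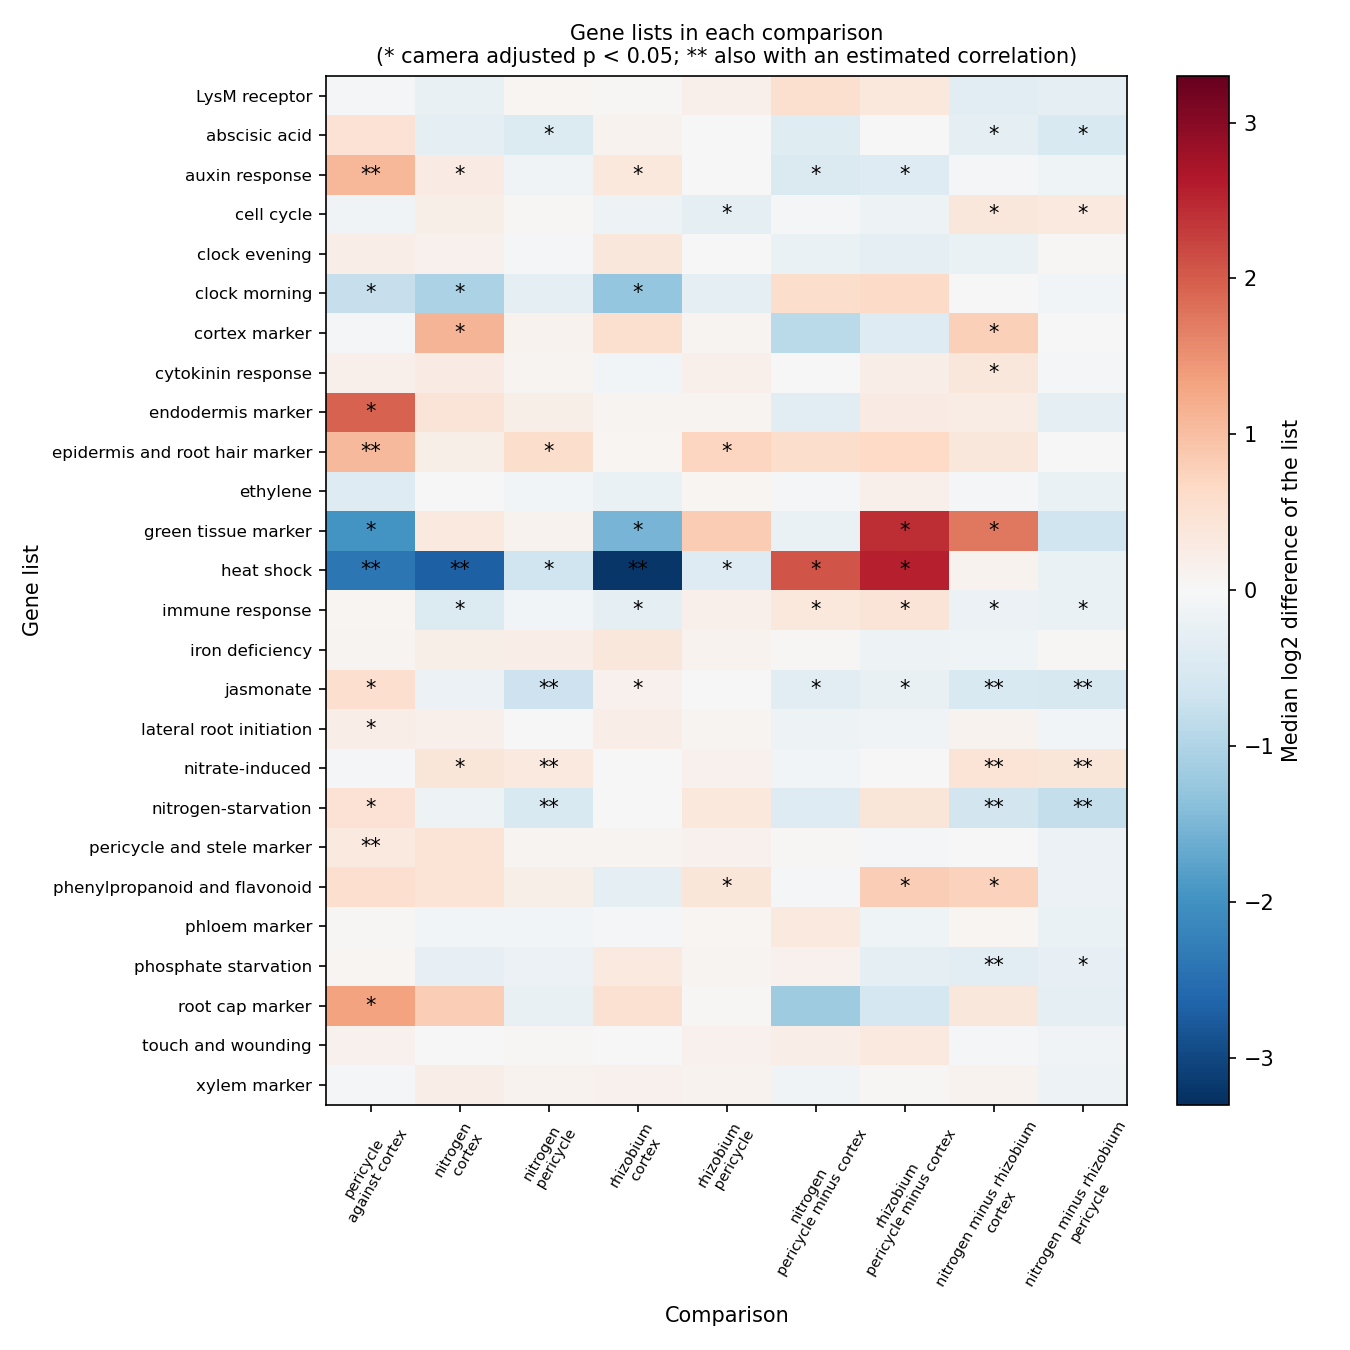
Median log2 difference (colour, from blue for lower to red for higher) of the gene lists (vertical axis) in 9 comparisons (horizontal axis), for the loci of each list; 1 star marks a camera adjusted p under 0.05 and 2 stars a call that also held with an estimated correlation. Nitrate-induced, nitrogen-starvation and jasmonate lists hold in the nitrogen response of pericycle and in nitrogen minus rhizobium in both cell types, and the heat shock list has the lowest medians, -2.70 and -3.21, in the cortex responses.

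Nitrogen and rhizobium calls overlapped in each cell type. In cortex 3484 loci were higher in both and 2531 lower in both, with 129 opposite, where independent lists of these sizes would share 1237 and 642.3, with 1783 opposite. The shared count of 6015 was 2804 with the heat shock covariate and 3650, 3739 and 3886 without replicate 1, 2 or 3. The changes correlated across loci at 0.743 (loci are not independent replicates), against 0.484 simulated for unchanged groups with the same standard arrays, and their covariance was 0.312 against 0.025. With the standard arrays split between the treatments the correlation was 0.622, the covariance 0.279 and the shared calls 1664 and 1351. Fewer standard arrays then also gave fewer calls, 8647 for nitrogen and 5453 for rhizobium. In pericycle 960 were higher and 1002 lower in both and 12 opposite, against 301.3, 266.5 and 597.2 for independent lists, with a correlation of 0.579 (simulated 0.521), a covariance of 0.108 (simulated 0.025), and 0.430, 0.088, 124 and 170 with split standard arrays. The split left 4146 nitrogen and 720 rhizobium calls in pericycle. The pericycle shared count of 1962 was 1077 with the covariate, 576 and 493 without replicate 1 or 3, and 1135 and 1262 without the 2 h or 6 h arrays. Between the cell types, the nitrogen responses shared 717 higher and 985 lower calls with 549 opposite, against 484, 444.9 and 972.2 for independent lists, and correlated at 0.232. The rhizobium responses shared 507 and 311, below the 770.3 and 384.7 of independent lists, with 1039 opposite, against 1090, and a correlation of 0.0046. For nitrogen minus rhizobium the counts were 537 and 881 with 23 opposite, against 122.1, 163.4 and 283.8, with a correlation of 0.396.

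Nitrate-induced genes were higher on cortex nitrogen than on cortex rhizobium arrays, and genes of nitrogen and phosphate starvation and of jasmonate were lower. The contrast does not say which treatment moved. The cortex jasmonate mean was 11.072 on nitrogen, 11.100 on standard and 11.645 on rhizobium arrays. The phosphate starvation mean was 8.48, 8.84 and 9.24 on the same arrays. Of 32 nitrate-induced genes 21 were higher and 1 lower (median 0.45), including AT3G25790 (2.30), LBD39 (1.95) and NIA1 (0.48 ± 0.09), and HB1 was higher by 3.69 ± 0.34 (adjusted p = 5.6e-17). Of 13 nitrogen-starvation genes 7 were lower (median -0.61), led by GLN1;4 (-1.62) and DUR3 (-1.53). Of 21 jasmonate genes 16 were lower (median -0.51, JAZ8 by -1.57), and of 13 phosphate starvation genes 6 were lower (median -0.34), among them MGD3 (-2.96 ± 0.28) and PLDZETA2 (-1.61) of lipid remodelling and the phosphate transporter gene PHT1;1 (-1.56). The malate synthase gene MLS (3.34), the trehalose phosphatase gene TPPB (2.92) and the aquaporin gene PIP2E (2.62) were higher, and HB53 (-4.05 ± 0.37) and GLR3.4 (-2.68) were lower.

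Further lists moved in the same comparison. Of 12 green tissue genes 10 were higher (median 1.75, RBCS2B by 2.82) and of 14 phenylpropanoid genes 8 were higher (median 0.77, CHS by 1.29), each with adjusted p = 0.060 with an estimated correlation. Higher too were 3 of 5 cortex markers (median 0.78), 3 of 16 cytokinin response genes (median 0.36) and 3 of 25 cell cycle genes (median 0.36), with adjusted p = 0.16, 0.087 and 0.36 with an estimated correlation. Of 12 abscisic acid genes 3 were lower (median -0.31) and of 22 immune genes 3 (median -0.20, WRKY53 by -1.02), with adjusted p = 0.16 and 0.29 with an estimated correlation. No heat shock gene passed (median 0.11), and the heat shock means of both sets of arrays were 11.39 and 11.20. The green tissue mean of cortex nitrogen arrays spread widely, at 9.63 ± 1.93.

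Between 32 nitrogen and 38 rhizobium cortex arrays 4020 loci passed the limma test, 1957 higher and 2063 lower (48.7% higher as deposited, 53.8% after centring). The nitrate-induced (camera adjusted p = 6.7e-14), jasmonate (2.8e-12), nitrogen-starvation (1.2e-05) and phosphate starvation (1.8e-04) lists held with an estimated correlation. The green tissue, phenylpropanoid, cytokinin, abscisic acid, cortex marker, immune and cell cycle calls did not. By p-values adjusted over the list alone, 22 nitrate-induced, 11 green tissue, 9 phenylpropanoid, 7 cytokinin and 3 cell cycle genes and 3 cortex markers were higher, and 18 jasmonate, 7 nitrogen-starvation, 6 phosphate starvation, 7 abscisic acid and 4 immune genes were lower. Without replicate 2 the count was 1774 and JAZ8 (-1.28) no longer passed, without replicate 1 CHS (0.98) did not, and over loci above the median level the cortex marker median was -0.13 and the phosphate starvation call ended (-0.12). The immune call ended without replicate 1 (-0.15) or 48 h (-0.09), the cytokinin call without replicate 2 (0.38), the cortex marker call without replicate 1 (0.67), 36 h (0.57) or 48 h (0.66), and the cell cycle call without replicate 1 (0.25) or 2 (0.29), 10 h (0.24) or 48 h (0.34).

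In pericycle the same contrast gave higher nitrate-induced genes and lower nitrogen-starvation and jasmonate genes. Of 32 nitrate-induced genes 19 were higher and 1, NRT3.1 (-2.05 ± 0.34), lower (median 0.40), including AT3G25790 (2.63 ± 0.36), HRS1 (1.61) and TGA1 (1.36), and HB1 was higher by 2.25 ± 0.32. Of 13 nitrogen-starvation genes 10 were lower (median -0.79): DUR3 by -2.92 ± 0.36, GLN1;4 by -1.76, NRT2.4 by -1.72, AMT1;1 by -1.17 and NRT2.5 by -0.79. Of 21 jasmonate genes 15 were lower (median -0.54), including JAZ9 (-1.71), LOX3 (-1.32) and AOS (-1.07), and outside the list DAD1 (-2.37), a lipase gene of jasmonate synthesis. Of 12 abscisic acid genes 7 were lower (median -0.50), including the biosynthesis gene NCED3 (-1.34), and 6 of 25 cell cycle genes were higher (median 0.31), 5 of them MCM genes such as MCM6 (1.68) and MCM4 (1.41), with adjusted p = 0.090 and 0.18 with an estimated correlation. Immune genes were lower in 7 of 22 and higher in 1 (median -0.23), and phosphate starvation genes lower in 4 of 13 and higher in 1 (median -0.27), with MGD3 at -2.40, and both lists had adjusted p = 0.18 with an estimated correlation.

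Between 41 nitrogen and 42 rhizobium pericycle arrays 3844 loci passed, 1694 higher and 2150 lower. The nitrate-induced (camera adjusted p = 7.3e-15), nitrogen-starvation (2.6e-17) and jasmonate (2.6e-17) lists held with an estimated correlation. The abscisic acid, cell cycle, immune and phosphate starvation calls did not. Adjusted over the list alone, 19 nitrate-induced genes were higher and 3 lower, 6 cell cycle genes were higher, and 11 nitrogen-starvation, 16 jasmonate, 8 abscisic acid, 8 immune and 5 phosphate starvation genes were lower. Higher calls were 44.1% as deposited and 29.1% after centring, and the phosphate starvation call (camera 0.040) ended after centring (-0.34), without replicate 2 (-0.07) or 4 (-0.29), and without 12 h (-0.27), 14 h (-0.28), 16 h (-0.26) or 36 h (-0.25). Without replicate 2 the count was 1259 and NRT2.4 (-1.52), NCED3 (-0.92) and MCM4 (1.13) no longer passed, and a fit of pericycle arrays alone gave 2409.

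Without treatment, morning clock genes followed the day in both cell types. From 12 h to the mean of 24 and 48 h, which are dawns, LHY was lower at 12 h by -6.39 ± 0.86 in cortex and -5.91 ± 0.86 in pericycle, CCA1 by -5.03 and -5.86, and LNK2 by -5.12 and -6.23. Of 11 morning clock genes 4 were lower at 12 h in cortex (median -2.96) and 5 in pericycle (median -1.96), and 8 and 6 adjusted over the list alone; camera gave 1.3e-13 and 6.3e-09, and both held with an estimated correlation (adjusted p = 4.2e-05 and 0.0022). No evening clock gene passed in either cell type over all loci (medians -0.05 and -0.29), and 1 was lower in pericycle adjusted over the list alone. Over all loci 269 differed in cortex and 1646 in pericycle, with 3 arrays at 12 h and 6 at 24 and 48 h in each. The order of the 2 counts is not stable, with 941 and 743 in a fit of each cell type alone, 412 and 9618 with array weights, and 306 and 60 without replicate 2. They were 33 and 40 without replicate 3, when CCA1 (-4.38) and LNK2 (-4.71) in cortex and LNK2 (-6.03) in pericycle no longer passed, as LNK2 in cortex did not without replicate 1 (-4.20).

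Other lists moved in the same comparison of hours. In cortex the 3 root cap markers had a median of 2.41 (camera adjusted p = 6.1e-04, adjusted p = 0.011 with an estimated correlation), with none past the test over all loci and 3 higher adjusted over the list alone, and the call ended without replicate 2 (0.93). Phenylpropanoid genes in cortex had a median of -0.81 with none past the test (adjusted p = 0.72 with an estimated correlation; -0.67 and no call without replicate 2). In pericycle 3 of 9 heat shock genes (median -2.09), 2 of 12 abscisic acid genes (-0.96) and 2 of 21 jasmonate genes (-0.25) were lower at 12 h, and 2 of 25 cell cycle genes higher (1.21), with adjusted p = 0.42, 0.13, 0.67 and 0.42 with an estimated correlation. With adjustment over the list alone 5 heat shock, 5 abscisic acid and 3 jasmonate genes were lower and 4 cell cycle genes higher. The jasmonate call ended without replicate 1 (-0.29) or 2 (-0.19) and the cell cycle call without replicate 2 (0.56).

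**Figure D5:**
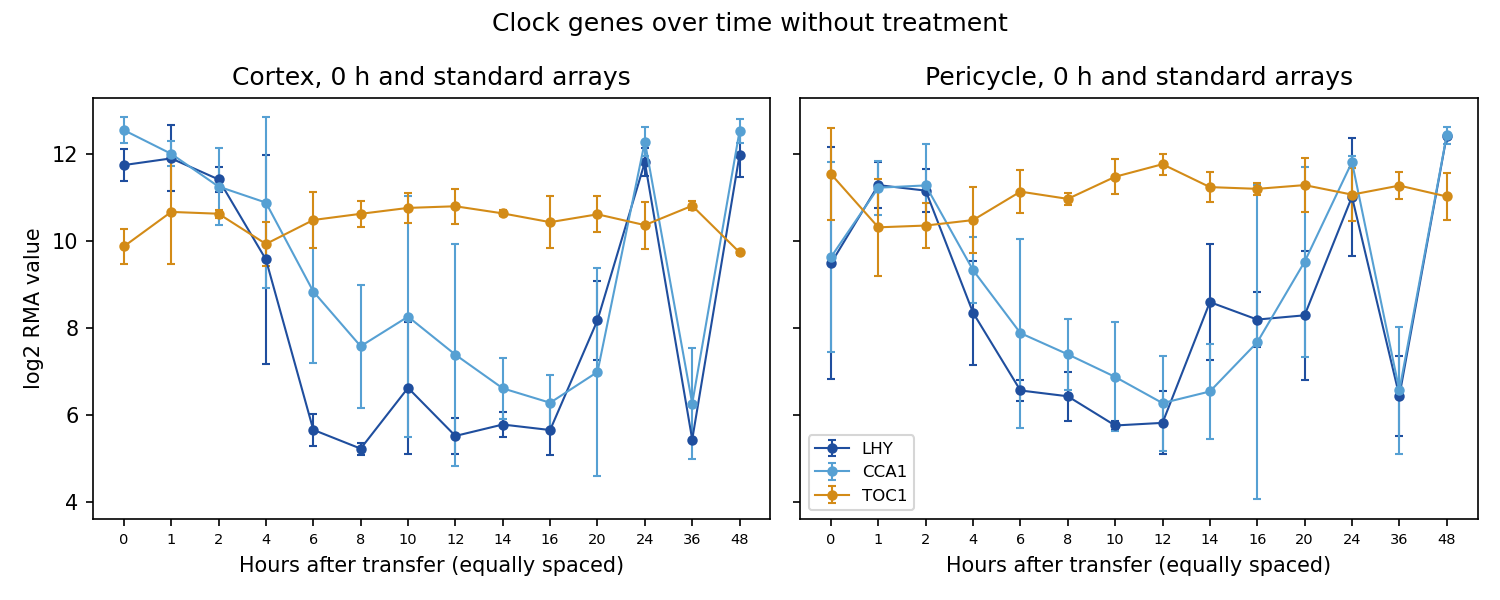
Mean log2 value ± SD (vertical axis) of LHY, CCA1 and TOC1 by hour (horizontal axis, hours equally spaced) on the 0 h and standard arrays of cortex (left) and pericycle (right), for 2 to 5 arrays a point. LHY stood at 11.82 ± 0.32 at 24 h and 5.52 ± 0.41 at 12 h in cortex, and TOC1 at 12 and 24 h was 10.81 and 10.37 in cortex.

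The standard time course against 0 h showed further genes by the moderated F test, 1596 in cortex and 3362 in pericycle. Fitted alone, cortex gave 3385 and pericycle 796, and with array weights the counts were 8369 and 10941, so neither their size nor their order is settled. In cortex LHY, the heat shock factor gene HSFA6B (-2.34 at 2 h), the glucosidase gene BGLU8 (5.70 at 6 h) and the terpene synthase gene TPS04 (6.38 at 1 h) were among the 5 loci with the smallest p, and in pericycle the sugar transporter gene SWEET4 (2.28 at 14 h), LHY and LNK2 (-5.41 at 16 h). The cortex course rests on 3 arrays at 0 h and the pericycle course on 5, of which 2 were among the 10 arrays with the lowest correlation to the others. Without replicate 3 the counts were 526 and 665, without those 10 arrays the pericycle count was 2020, and SWEET4 (2.27) no longer passed without replicate 2.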

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

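Among the tests below, the comparison of cortex standard with rhizobium arrays, the heat shock difference at 1 h and the comparison of endodermis with xylem markers were chosen after the result was seen.

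Heat shock genes were higher on the cortex standard arrays than on the treated cortex arrays. The cortex standard mean exceeded the cortex rhizobium mean by 3.02 log2 units, with an SD of 0.78 between standard arrays, which argues against low nitrate alone, since the rhizobium plates held 0.1 mM KNO3 too. Scaling is argued against too, since the smaller of the cortex list shifts under centring or quantile normalization was 2.61 in size. Heat or handling of the cortex standard material may be the source, and predicted a difference in full at 1 h that does not grow: the treatments lay at -2.52 relative to standard at 1 h but at -3.67 at 48 h, so it grew and the prediction was not met in full. With 3 arrays per group at 1 h this cannot be told apart from a fast response to both treatments, and both stay open.

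Rhizobium calls in pericycle lay almost all in the early window. Scaling and low-correlation arrays are argued against, since the lower early count under 2 scalings was 5032 and the count without the 10 arrays of lowest correlation was 5152. With a replicate block the early count stayed within 1.5 times its value, which covers only a shift common to all pericycle arrays of a replicate number. A structure of replicate 3 arrays that differs between treatments or hours stays open. The early count fell far more without replicate 3, as given above, though fewer arrays also give fewer calls. In pericycle 28.3% of array pairs within replicate 3 had residual correlations above 0.1. The highest label split gave 3378 early calls. The main axes of unexplained variation between replicates are a candidate explanation: 54.2% of the squared length of the early change lay along 5 components of the replicate deviations, against 35.5% for nitrogen early and 17.5 to 30.2% for the other windows. An early response to the bacterium stays open and was not tested apart from this.

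Endodermis and root hair markers were higher on pericycle than on cortex arrays, as for CASP1 (11.57 against 7.50), ESB1 (11.16 against 6.71) and RHD6 (10.42 against 7.31). A lower share of sorted pericycle cells with all other types alike is argued against, since the endodermis median lay 2.00 log2 units above the xylem median. Carry-over of outer root cells in varying amounts is a candidate explanation, although sorting on the marker should remove them: over 125 pericycle arrays, deviations of the endodermis and root hair means correlated at 0.453 (permutation p = 1e-05, the smallest that 100000 permutations can give). Endodermis deviations correlated at -0.566 with xylem markers. They correlated at 0.171 with pericycle and stele markers, which carry-over that dilutes the sorted cells would make negative. With cortex markers they correlated at -0.503, which carry-over that includes cortex cells would make positive. The pericycle and cortex values go against carry-over of these kinds. Expression of these genes in the sorted cells themselves stays open and was not tested.

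The nitrogen responses of the cell types differed at 6175 loci by the test of the difference, with list medians of 2.09 for heat shock, 0.34 for immune response, -0.48 for auxin response and -0.37 for jasmonate. The rhizobium responses differed at 9060 loci, with medians of 2.56 for heat shock, 2.45 for green tissue, 0.43 for immune response, 0.81 for phenylpropanoid and flavonoid, -0.43 for auxin response and -0.26 for jasmonate. None of these list calls held with an estimated correlation (adjusted p = 0.061 to 0.35 for nitrogen and 0.065 to 0.50 for rhizobium), and the differences contain the cortex standard arrays.

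Of 40 comparisons within groups of 4 or 5 arrays, 2 had an array far from the others, where chance gives about 1 in 20. The heat shock mean of pericycle rhizobium 12 h replicate 2 was 9.45 with the nearest at 12.22, and the jasmonate mean of pericycle 0 h replicate 1 was 10.50 with the nearest at 12.09.

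Chance was examined with 100 label splits for each count, the real one included. Each count was judged alone, with no correction over the counts, and 1 of 100 is the smallest share possible. The splits treat arrays as independent, so chance here means chance between arrays. Chance is excluded, with 1 of 100 splits as large, for cell type (10630, highest other 492), the nitrogen mean response (cortex 9687 and 437, pericycle 5327 and 108), the rhizobium mean response (10264 and 247, 5936 and 653), the differences between cell types (nitrogen 6175 and 8, rhizobium 9060 and 5) and nitrogen against rhizobium (4020 and 8, 3844 and 1165). It is also excluded for nitrogen in the early (2260 and 438, 1795 and 833), middle (4510 and 255, 1692 and 616) and late windows (3981 and 510, 2350 and 472), and at any time (4506 and 934, 2832 and 1454). The same holds for rhizobium early (1717 and 362, 6292 and 3378), middle in cortex (5935 and 1480), late in cortex (3842 and 109) and at any time (3654 and 946, 4035 and 2134), and for the standard courses (1596 and 669, 3362 and 2251). For rhizobium late in pericycle 1 of 100 splits was as large (47, highest other 14). Centring left no call there, and with this many counts judged alone chance is not excluded for it. For the clock in cortex 1 of 100 splits was as large (269, highest other 253). For the clock in pericycle 4 of 100 gave as many as 1646, the highest 2105. Few arrays were shuffled for the clock, and with this many counts judged alone neither result excludes chance. For rhizobium middle in pericycle 11 of 100 gave as many as 25, the highest 1245, so chance is not excluded, and a split that calls many times the real count points to a structure of the samples.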

How the results depend on the processing

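The heat shock covariate, leaving out the 10 arrays of lowest correlation and counting the near-identical pair as 2 arrays were tests chosen after the result was seen. Over all alternatives 560 of 762 counts stayed within 1.5 times their value and 202 moved. Of 7269 values for genes named or cited for a contrast 7223 kept direction and side of the threshold and 46 no longer passed. Of 373 values for F tests, which have no direction, 371 kept the side and 2 no longer passed. These genes were picked mostly because they passed in these data, many with the largest changes. Their share is therefore largely set by that choice and does not measure how stable other calls are. Of 8369 list values 8081 kept their side of the threshold, 114 no longer passed, 172 newly passed and 2 reversed. Direction was compared only for lists that passed as reported, so the 8081 include lists without a call whose sign was not checked. Counts moved in 0 of 32 with the trended robust prior, the near-identical pair as 2 arrays and the replicate block (clock cortex 304 with the block against 269). The cause was not tested for the changes below, except where fewer loci or arrays or a stricter threshold give fewer calls by construction. Array signal over background was not examined.

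With an adjusted p below 0.01, counts in cortex then pericycle were: clock 87 and 693; nitrogen any-time 2986 and 1356, early 827 and 463, middle 2544 and 659, late 2396 and 1212; nitrogen against rhizobium 2286 and 1843; overlap 3861 and 698; rhizobium early 736 and 3481, middle 3551 and 2, late 1821 and 0; standard course 844 and 1535. In pericycle the nitrogen mean was 2929, the rhizobium mean 3157 and rhizobium any-time 1767, and the differences between cell types were 3633 for nitrogen and 5843 for rhizobium.

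With a log2 change of at least 1, counts in cortex then pericycle were, for nitrogen, mean 2551 and 1043, early 1421 and 952, middle 2594 and 984, late 2613 and 1427; for rhizobium, mean 2730 and 659, early 1096 and 3113, and in cortex middle 3426 and late 2233; for nitrogen against rhizobium 1208 and 708; for the overlap 1335 and 178. Cell type gave 3022, the nitrogen difference 2825 and the rhizobium difference 3898.

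With each cell type fitted alone, cortex then pericycle gave clock 941 and 743; nitrogen any-time 8643 and 863, early 4893 and 399, middle 6993 and 813, late 6068 and 1492; nitrogen against rhizobium 6316 and 2409; rhizobium any-time 6332 and 817, late 6234 and 0; standard course 3385 and 796. Rhizobium early in cortex was 3358, rhizobium middle in pericycle 1 and the pericycle overlap 1023.

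With array weights, cortex then pericycle gave clock 412 and 9618, nitrogen any-time 11654 and 7095, rhizobium any-time 10609 and 11383, and standard course 8369 and 10941. In cortex nitrogen middle was 7089, nitrogen late 9917, nitrogen against rhizobium 7159, rhizobium early 6587 and rhizobium late 7895, and in pericycle rhizobium middle was 818.

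Above the 25th percentile the clock in cortex was 149, and in pericycle rhizobium mean 3762, early 3973, middle 14, late 12 and standard course 2015. Above the 50th percentile cell type was 5699, the clock in cortex 95, nitrogen any-time in cortex 2891, nitrogen early 1438 and 1083 in cortex and pericycle, nitrogen mean in cortex 5548, the nitrogen difference 4045 and the overlap 3664 and 1101. Rhizobium any-time was 2409 and 1879, early in pericycle 2490, late 2295 and 24, mean 6060 and 2416, the rhizobium difference 5274 and the standard course 876 and 1262. The cortex marker list in nitrogen against rhizobium in cortex reversed, from 0.78 to -0.13.

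With the heat shock covariate, nitrogen in cortex gave mean 5074, any-time 1595, early 951 and middle 2365, and early in pericycle 1161; rhizobium in cortex gave mean 5405, any-time 763, early 1071, middle 3128 and late 1608, and late in pericycle 2; the overlap gave 2804 and 1077. The morning clock list in pericycle against cortex reversed, from -0.76 to 0.053. Since the covariate nearly separates cortex standard from treated cortex arrays, it takes up much of the treatment difference there. Fewer calls in cortex with it are thus partly by construction.

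Of the 61 list calls in the 9 mean comparisons, 16 held with an estimated correlation, and fry made 128. Without the 10 arrays of lowest correlation nitrogen early in cortex was 1158 and the pericycle standard course 2020. With split standard arrays the overlap was 3015 in cortex and 294 in pericycle. The rhizobium calls themselves fell with the fewer standard arrays, from 10264 to 5453 in cortex and from 5936 to 720 in pericycle. The lower overlap is thus not a measure of lost sharing. Without 2 h the rhizobium mean in pericycle was 3943 and the pericycle overlap 1135, and without 6 h that overlap was 1262. Rhizobium late in pericycle was 0 after centring, 21 after quantile normalization and 19 with 1 test per table entry; this is a limma count of 47 as reported, with 3697 loci at an unadjusted p below 0.05.

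Leaving out each replicate number in turn gave these lowest and highest counts. Where a group was left with 1 array, that array is assumed to vary like the other groups. Cell type: 5892 (without replicate 1) to 10697. Nitrogen in cortex: mean 6411 (2) to 9819, any-time 1929 (3) to 4682, early 443 (2) to 2460, middle 1578 (1) to 4636, late 1905 (2) to 4053. Nitrogen in pericycle: mean 1759 (1) to 5681, any-time 815 (1) to 3638, early 70 (3) to 2291, middle 230 (1) to 1710, late 987 (1) to 2413. Rhizobium in cortex: mean 6788 (2) to 10362, any-time 1475 (3) to 3718, early 287 (3) to 1778, middle 2997 (3) to 6057, late 949 (2) to 3932. Rhizobium in pericycle: mean 1200 (3) to 5957, any-time 193 (3) to 4111, early 534 (3) to 6315, middle 1 (3) to 54, late 1 (3) to 53. Differences between cell types: nitrogen 3421 (1) to 6193, rhizobium 4745 (3) to 9075. Nitrogen against rhizobium: cortex 1774 (2) to 4130, pericycle 1259 (2) to 3867. Overlap: cortex 3650 (1) to 6102, pericycle 493 (3) to 2016. Clock: cortex 33 (3) to 350, pericycle 40 (3) to 3894. Standard course: cortex 526 (3) to 1651, pericycle 665 (3) to 3206. List calls: 58 to 71.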

Other observations

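Lists without a call in the mean comparisons are given here as values. In the cortex rhizobium response iron deficiency genes were higher in 8 of 16 and lower in 1 (median 0.37, camera adjusted p = 0.13), evening clock genes higher in 4 of 9 (median 0.37, 0.17) and ethylene genes higher in 1 and lower in 3 of 11 (median -0.21, 0.11). In pericycle against cortex, phloem markers had 2 of 5 higher and 1 lower (median 0.03, 0.39) and xylem markers 1 of 8 higher and 2 lower (median -0.06, 0.39). Touch and wounding genes had 2 of 5 higher in the pericycle rhizobium response (median 0.15, 0.072). LysM receptor genes were lower in 4 of 8 in nitrogen against rhizobium in pericycle (median -0.32, 0.16).

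Some lists by window are given as values, which were not recomputed with replicates or hours left out or with other scalings. Abscisic acid genes in nitrogen-treated pericycle were lower in 8 of 12 over 20 to 48 h (median -1.11, adjusted p = 0.0027 with an estimated correlation). Phenylpropanoid genes rose in 9 of 14 over 1 to 6 h in rhizobium-treated pericycle (median 0.76), with adjusted p = 0.49 with an estimated correlation. Immune genes fell in 7 of 22 over 20 to 48 h in nitrogen-treated cortex (median -0.47, adjusted p = 0.019 with an estimated correlation). Cortex markers rose in 3 of 5 there (median 1.86, adjusted p = 0.028 with an estimated correlation).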
